A study of Homo sapiens with 6 samples.

How the data were processed

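Small RNAs were sequenced from HCT116 cells lacking DICER, a human colorectal carcinoma cell line whose own DICER gene was knocked out, after transfection with a plasmid that restores either full-length DICER (DICER-WT rescue, 3 samples) or DICER with its helicase domain removed (DICER-delHelicase rescue, 3 samples). Per the labels' protocols, RNA was taken 48 h after transfection, a small RNA fraction was cut from a 12% urea gel loaded with 10 µg of total RNA, and libraries were made with an Illumina TruSeq small RNA kit. Cutadapt, Bowtie2 and bedtools and the genome build GRCh38 are named in the submitters' processing notes, where their versions, order and settings are not given in the sources used here.

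The table used here holds 1 line per microRNA hairpin and DICER construct, 294 lines in all. Its main value is a variation score, per the file headers a "global variation", which the authors deposited as a single number for each construct. Neither the formula of that score nor the way the 3 samples of a group were combined into it (pooled reads, a mean or part of the samples) is given in the sources used here. The scores reached values above 1 and were not whole, so they were neither fractions nor read counts. The header ties 2 further columns to the DICER-WT libraries. One, headed as the major 5′ end, holds whole numbers. These were read here as the offset of the main 5′ end of each miRNA, in nucleotides from a reference position 0. The header gives neither the unit nor that position. The other is a Yes or No class headed 2-nt. Both columns held the same entry for a hairpin in the lines of both constructs. The table names the construct of a line but no replicate. No spread between the 3 samples of a group could therefore be computed, no test between the groups was run, and the labels give no sign whether the samples of a group came from separate cultures. The depth behind the scores is unknown, so neither an interval nor a detection limit was attached to a single score.

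For each of 147 hairpins the WT score was subtracted from the delHelicase score. Before the data were examined, a separate plan had been fixed for a table without sample columns, and that plan was followed: the distribution of the values, the 10 largest and 10 smallest changes, a set of preset miRNAs (miR-451a, miR-320a, miR-484, let-7a, let-7i, miR-21, miR-200b and miR-16) and up to 4 examples from each of 23 fixed miRNA lists. The plan speaks of the largest and smallest values, which was read here as changes. Examples were to be the most abundant members. The table gives no abundance, so members were taken in alphabetical order of miRNA name. The count tests, the cleavage-site tests, the per-library homogeneity and the arm-ratio comparison planned for other kinds of tables were not run, since they need values per sample. The plan had assumed counts or shares per library, and the table held a score, so only the part of the plan written for such a table applied. Further members of the let-7 and miR-30 lists, and the let-7a copies as an exception among copies, were named after their values were seen. The comparisons by 2-nt class, by offset and between copies, and the search for stretches shared by miR-30 hairpins, were likewise chosen after the table was seen.

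Each list with at least 3 hairpins from at least 3 miRNAs was described by the percentile of its median change among 10000 random lists of the same size drawn from all hairpins. Matching on expression was not possible, and a match on the WT score in 5 bins was added after the data were seen. The percentile describes these scores and is not a p-value between conditions. The procedure was tested on simulated tables in which the observed changes of the 147 hairpins, centred on their median, were shuffled, with 500 random lists per table. There a list of 5 hairpins reached the 97.5 percentile in 3 of 100 tables with no added change. It did so in 44 of 100 with 0.3 added and in 100 of 100 with 0.6 added. These rates are for 1 list, not for the highest of the 10 lists that received a percentile. They also hold for independent list members, whereas members of a family can be related or share reads. Differences between the 2-nt classes were set against 10000 random relabelings of the hairpins. Correlations with hairpin features were set against 100000 permutations, and the follow-up tests of loop size against 10000. Alternatives tried were 1 value per miRNA, means in place of medians and hairpins with a mean score above the median, and, chosen after the table was seen, miRNAs with a single hairpin, hairpins with offset 0, changes of at least 0.05 and the match on the WT score. Shares of hairpins are given with exact Clopper-Pearson 95% intervals, which treat hairpins as independent and hold no error between samples.

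The table lists 127 miRNAs, 111 with a single hairpin and 16 with several hairpins (36 hairpins together). Copies of a miRNA can share reads, so results are also given with 1 mean value per miRNA. Hairpin sequences were matched to GENCODE release 29 miRNA transcripts on GRCh38, the build the notes name. Of 147 hairpins, 145 contained an annotated hairpin, 4 of them several, which were settled by name, and 2 had no match (mir-10399 and mir-320b-2). In 139 of these the deposited sequence extended the annotated hairpin by 10 nt on each side. The coordinates printed are those of the annotated hairpin, counted from 1. Secondary structures were predicted with ViennaRNA 2.7.2 at its default settings on the deposited sequences. The size of the apical loop was the length of the unpaired run that closes the predicted hairpin. Where several such runs were predicted, the one nearest the midpoint was used. Loop sizes of the copies of a miRNA were averaged. This size does not measure the full stretch that DICER removes. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.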

Results

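The deposited values describe how 147 microRNA (miRNA) hairpins were processed in HCT116 cells without endogenous DICER, a colorectal carcinoma line, after rescue with full-length DICER or with DICER lacking its helicase domain. DICER is the RNase III enzyme that removes the apical loop of a precursor miRNA, and its cut sets the 5′ end of the miRNA from the 3′ arm (3p). Of the 127 miRNAs in the table, 113 carry 3p in their name and 14 carry no arm. Each hairpin had 1 variation score for the DICER-WT rescue and 1 for the DICER-delHelicase rescue, and each group had 3 samples. How the samples of a group entered its score is not given in the sources used here. The depth of the samples is unknown, and no value per sample was given, so none of the differences below has a replicate check.

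The main comparison asked whether the removal of the helicase domain changed the variation of DICER products. Scores were higher with DICER-delHelicase than with DICER-WT for most hairpins. Whether the score counts from the main DICER-WT end in both groups is not given. Such a count could itself favour higher delHelicase scores. The delHelicase score was the lower one in 38 of 147 hairpins, equal in 3 and the higher one in all others (72.1%, exact 95% interval 64.1 to 79.2). The median score was 0.0804 with DICER-WT (quartiles 0.0174 and 0.187) and 0.146 with DICER-delHelicase (quartiles 0.0260 and 0.351), a ratio of medians of 1.82. The median change per hairpin was 0.0261 (quartiles -0.000436 and 0.157). With 1 value per miRNA, 89 of 127 were higher, 35 lower and 3 equal. Among the 29 hairpins with the highest DICER-WT scores, 16 were higher and 13 lower (55.2% higher, exact 95% interval 35.7 to 73.6), with a median change of 0.114.

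Large differences were mostly increases with DICER-delHelicase. A change of at least 0.05 was an increase in 68 hairpins and a decrease in 17. At 0.1 or more the counts were 55 and 11, and at 0.2 or more they were 30 and 4. Scores above 0.5 were found in 9 hairpins with DICER-WT and in 27 with DICER-delHelicase. Scores under 0.05 were found in 59 and 47 hairpins. No score was below 0. If none can be, a hairpin could fall by at most its DICER-WT score, and the upper quartile of those scores was 0.187. Increases had no such limit, so the counts of large changes favour increases. Across the 127 miRNAs the scores of the rescues were related (Spearman's rho 0.787, Pearson's r 0.553), a relation across miRNAs, which are not independent replicates.

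**Figure D1:**
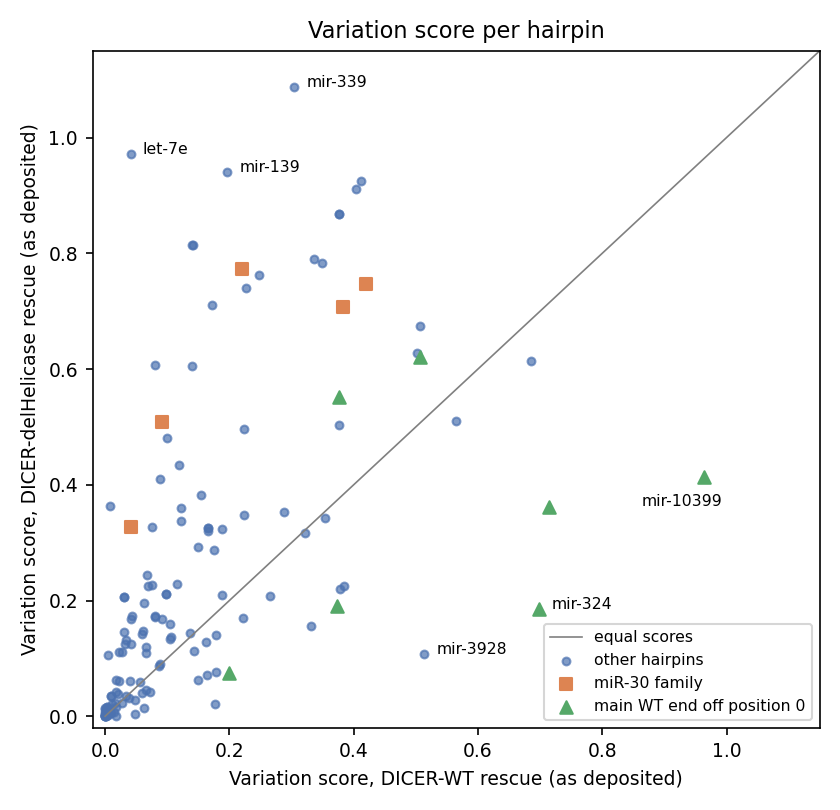
Variation score of each of 147 hairpins with DICER-WT (x axis) and with DICER-delHelicase (y axis), both as deposited and without a unit, 1 point per hairpin. Of these, 72.1% lie above the line of equal scores; the 5 squares are miR-30 hairpins, and the 7 triangles are hairpins whose main WT end is off position 0.

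The hairpin with the largest increase was let-7e, of the let-7 family, which is listed for the 3′ arm miRNA let-7e-3p. Its score was 0.0409 with DICER-WT and 0.972 with DICER-delHelicase. The annotated hairpin lies on chromosome 19 from 51692786 to 51692864 (plus strand, GRCh38), in an intron of SPACA6. The deposited hairpin sequence was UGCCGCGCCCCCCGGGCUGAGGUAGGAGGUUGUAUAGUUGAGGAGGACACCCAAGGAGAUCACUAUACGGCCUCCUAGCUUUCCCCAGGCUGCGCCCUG. The score of mir-339 went from 0.304 to 1.09, the highest score in the table. Its hairpin lies on chromosome 7 from 1022933 to 1023026 (minus strand), in an intron of C7orf50. For mir-139, on chromosome 11 from 72615063 to 72615130 (minus strand) in an intron of PDE2A, the scores were 0.196 and 0.940.

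Other hairpins among the 10 largest increases included both mir-3158 copies, each with 0.814 under DICER-delHelicase against 0.141 (mir-3158-1) and 0.140 (mir-3158-2) under DICER-WT. These copies are annotated on opposite strands of a single interval of chromosome 10, from 101601417 to 101601497, and their reads may not be separable. The mir-30c-1 hairpin, in an intron of NFYC on chromosome 1 (40757284 to 40757372, plus strand), had scores of 0.221 and 0.773. The score of mir-28, in an intron of LPP on chromosome 3 (188688781 to 188688866, plus strand), was 0.171 with DICER-WT and 0.710 with DICER-delHelicase. For mir-424, in an exon of the long non-coding RNA MIR503HG on chromosome X (134546614 to 134546711, minus strand), it was 0.0804 and 0.608. The scores of mir-126 were 0.248 and 0.763. Those of mir-7-1, in an untranslated exon of HNRNPK on chromosome 9 (83969748 to 83969857, minus strand), were 0.226 and 0.741.

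Decreases were fewer and smaller, and a low DICER-WT score left little room for one. The largest was that of mir-10399, from 0.964 with DICER-WT to 0.413 with DICER-delHelicase. For mir-324, on chromosome 17 from 7223297 to 7223379 (minus strand) and outside other genes on that strand, the score was 0.698 with DICER-WT and 0.185 with DICER-delHelicase. Its deposited sequence was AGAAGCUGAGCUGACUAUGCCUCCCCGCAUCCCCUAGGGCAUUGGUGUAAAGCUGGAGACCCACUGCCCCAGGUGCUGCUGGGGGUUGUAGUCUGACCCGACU. The scores of mir-3928, on chromosome 22 from 31160062 to 31160119 (minus strand), were 0.513 and 0.108. Those of mir-145, listed for miR-145-3p and in an intron of the long non-coding RNA CARMN on chromosome 5 (149430646 to 149430733, plus strand), were 0.714 and 0.361. Then followed mir-425 (0.374 and 0.191), mir-151a (0.331 and 0.155), the copies mir-101-1 (0.385 and 0.225) and mir-101-2 (0.377 and 0.220), mir-106b (0.177 and 0.0215) and mir-16-2 (0.199 and 0.0749), each with the DICER-WT score first.

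**Figure D2:**
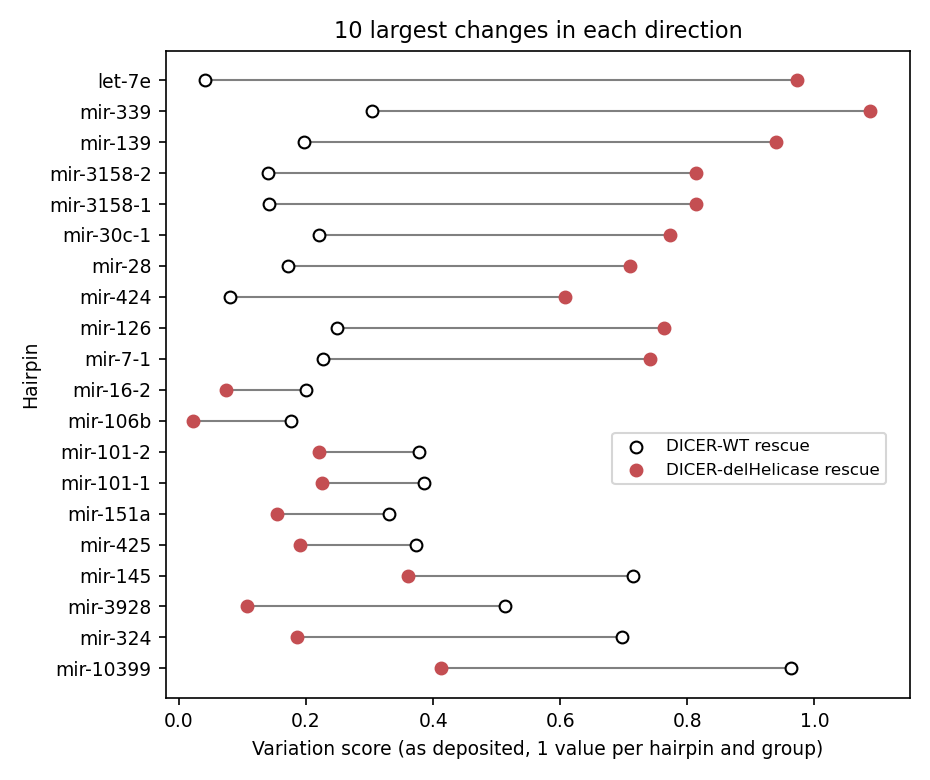
Variation scores (x axis, as deposited, without a unit) of the 10 hairpins with the largest increase and the 10 with the largest decrease, 1 hairpin per line; open circles are DICER-WT and filled circles DICER-delHelicase. The increases reach 0.931 in let-7e, and the largest decrease is -0.551 in mir-10399.

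Among the families fixed beforehand, miR-30 had the largest median change of those with more than 1 hairpin. All 5 of its hairpins scored higher with DICER-delHelicase, by 0.286 to 0.552, and the family median went from 0.221 to 0.708. The scores were 0.420 and 0.746 for mir-30a, 0.0410 and 0.327 for mir-30b, 0.383 and 0.708 for mir-30d, and 0.0917 and 0.508 for mir-30e, with mir-30c-1 given above. The median change of 0.326 lay at the 98.0 percentile of random lists and at 97.7 with 1 value per miRNA. Among lists matched on the DICER-WT score it lay at 95.5. The value of 98.0 was the highest among the 10 lists that received a percentile, and no adjustment for their number was made. No pair of these 5 hairpins shared more than 18 identical nucleotides in a row in the part from the midpoint to the 3′ end. That search covered exact runs only, and the mapping settings are not given. It therefore does not show that the reads of these hairpins were separable.

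The let-7 and miR-98 family also scored higher with DICER-delHelicase, in 6 of 7 hairpins, with a median change of 0.167 at the 94.7 percentile of random lists, 91.7 with 1 value per miRNA and 89.0 among lists matched on the DICER-WT score. Scores were 0.154 and 0.382 for let-7a-1, 0.507 and 0.674 for let-7a-3, 0.0416 and 0.124 for let-7f-1, 0.0755 and 0.327 for let-7f-2, and 0.149 and 0.292 for mir-98. The exception was let-7d, with 0.221 and 0.171. The group II precursors, which are known to be monouridylated before dicing, comprised 6 of these hairpins, 5 of them higher (median change 0.155, 89.9 percentile, 87.7 with 1 value per miRNA and 75.8 among matched lists). Group I was represented by let-7e alone.

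All 7 hairpins of the miR-320 family, entered in the fixed lists as made without DROSHA, scored higher with DICER-delHelicase, by 0.0562 to 0.131 (median 0.112, 80.5 percentile). They stand for 4 miRNAs, and with 1 value per miRNA the percentile was 70.7. All 7 hairpins share an identical stretch in their 3′ part, so the reads of these miRNAs may not be fully separable. The scores were 0.104 and 0.160 for mir-320a, 0.0980 and 0.210 for mir-320b-1, 0.0983 and 0.212 for mir-320b-2, and 0.0807 and 0.173 for mir-320c-1. In the group of miR-103 and miR-107, which lies in introns of the PANK genes, mir-103a-1 scored 0.0304 and 0.206, mir-103a-2 0.0304 and 0.207, and mir-107 0.0116 and 0.0211. The single miR-21 hairpin, mir-21, listed for miR-21-3p, had 0.187 and 0.324. Both miR-181 hairpins were higher (0.00529 and 0.106 for mir-181a-2, 0.0914 and 0.168 for mir-181a-1). Of the pair mir-221 and mir-222, mir-221 had 0.00237 and 0.00391, and mir-222 had 0.0274 and 0.110.

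In several families the differences were small or went in both directions. In the miR-200 family, which maintains the epithelial state, 3 of 4 hairpins were higher (0.00966 and 0.0351 for mir-200a, 0.0687 and 0.224 for mir-200b, 0.0183 and 0.0414 for mir-200c), and mir-429 was lower (0.0622 and 0.0147). Its median change of 0.0243 lay at the 36.4 percentile, and at 19.1 among lists matched on the DICER-WT score. The miR-17-92 cluster with its paralogs, a MYC-driven group, held 5 higher and 4 lower hairpins, with a median change of 0.00267 and a mean change of -0.00101 (14.2 percentile, 22.7 with 1 value per miRNA). Here mir-18a scored 0.104 and 0.133, mir-19a 0.0564 and 0.0591, and mir-19b-1 0.00517 and 0.00395. Of the 6 hairpins of the miR-23/27/24 clusters 5 were higher, with a median change of 0.0116 and a mean of 0.0259. The median lay at the 28.9 percentile of random lists, at 38.4 with 1 value per miRNA and at 63.8 among lists matched on the DICER-WT score. Examples are mir-23a (0.0201 and 0.0388), mir-23b (0.0305 and 0.146), mir-24-1 (0.00368 and 0.0153) and mir-24-2 (0.00368 and 0.0152).

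In the miR-15/16 group the median change was 0.000442 (18.96 percentile) and the mean 0.134, with mir-15b at 0.00463 and 0.00507, mir-16-2 lower and mir-424 higher, as given above. The group of miR-148 and miR-152 had the lowest median scores of the lists with either construct, 0.000696 and 0.00129 for mir-148a, 0.00147 and 0.00124 for mir-148b and 0 in both for mir-152 (17.4 percentile). Of the list of miR-99, miR-100 and miR-125 hairpins, mir-125a (0.178 and 0.0760) and mir-125b-1 (0.0590 and 0.0407) were lower and mir-99b (0.00900 and 0.0351) was higher, with a median change of -0.0183 (7.58 percentile, 3.64 among lists matched on the DICER-WT score). The scores of mir-29a were 0.506 and 0.620, while mir-29b-1 (0.163 and 0.128) and mir-29b-2 (0.143 and 0.113) were lower, so that the median change of this list was -0.0297 and its mean 0.0165. The mir-10a hairpin scored 0.321 and 0.316. Of the list of miRNAs typical of other cell types or serum, 4 hairpins were found, all higher: mir-126, an endothelial miRNA in an intron of EGFL7, and 3 copies of the neural mir-9, the first 2 of which (mir-9-1 and mir-9-2) had 0.166 and 0.325. The remaining lists (miR-34, miR-192 with miR-194 and miR-215, miR-26, the DICER-independent miR-451a and the mirtrons) had no hairpin in the table, nor had the preset miR-484 and let-7i.

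**Figure D3:**
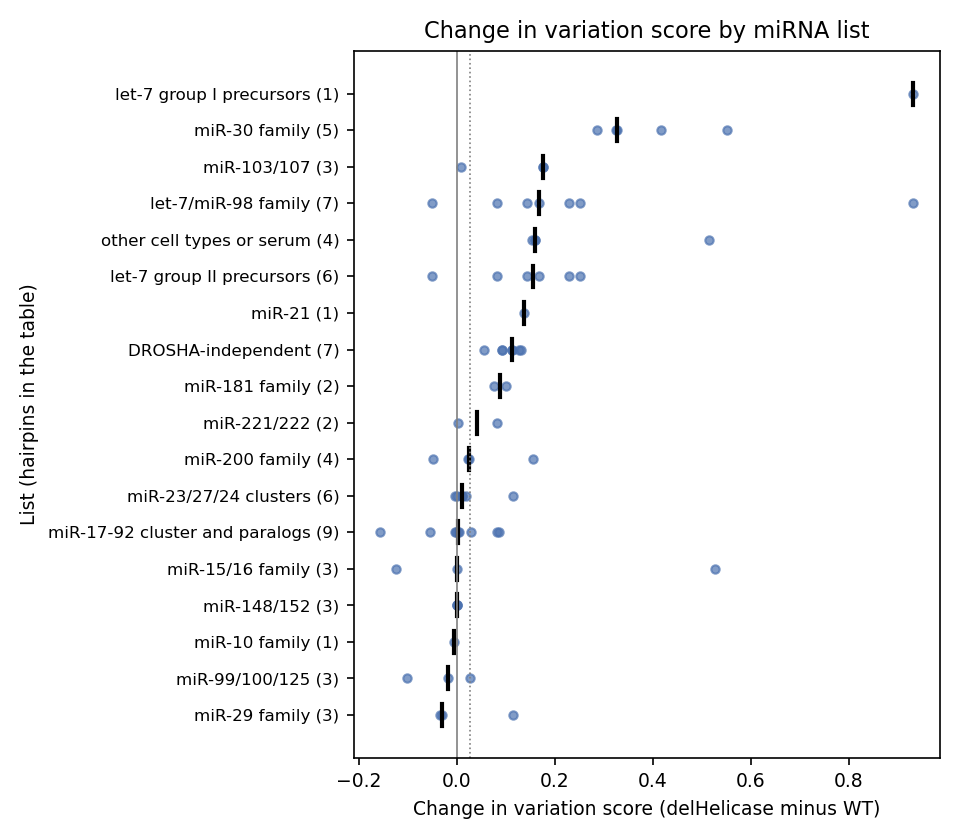
Change in variation score (delHelicase minus WT, x axis, without a unit) of each hairpin in 18 miRNA lists, with the number of hairpins in parentheses; points are hairpins, black bars are list medians, the solid line is 0 and the dotted line is the median of all hairpins, 0.0261. The miR-30 points lie between 0.286 and 0.552, and the list medians lie on both sides of 0.

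The table also divides the hairpins into a 2-nt class (Yes for 73, No for 74), derived from the DICER-WT products. The delHelicase score was higher in 51 of 73 hairpins with Yes (69.9%, exact 95% interval 58.0 to 80.1) and in 55 of 74 with No (74.3%, 62.8 to 83.8). Median scores were 0.0807 and 0.146 in the Yes class and 0.0752 and 0.146 in the No class. The median change was 0.0115 for Yes and 0.0549 for No. The difference of -0.0434 lay within the middle 95% of random relabelings (-0.0743 to 0.0739), and so did that over miRNAs with a single hairpin, -0.0179.

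The offset of the main DICER-WT 5′ end was 0 in 140 hairpins and different from 0 in 7. Of the 140, 104 scored higher with DICER-delHelicase, 33 lower and 3 equal. The 7 others had higher DICER-WT scores (median 0.506 against 0.0706), and 5 of them scored lower with DICER-delHelicase, namely mir-10399 (offset -4), mir-324 (3), mir-145 (2), mir-425 (-1) and mir-16-2 (-1). The remaining hairpins of this set, mir-203a (offset 1, scores 0.377 and 0.551) and mir-29a (offset -1), scored higher.

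Copies of a miRNA mostly had near-identical scores. In 15 of the 16 miRNAs with copies, the DICER-WT scores of the copies differed by at most 0.0197. The exception was let-7a-3p, whose copies let-7a-1 (chromosome 9, 94175957 to 94176036, plus strand, in an intron of a long non-coding RNA) and let-7a-3 (chromosome 22, 46112749 to 46112822, plus strand, in an exon of MIRLET7BHG) differed by 0.353 with DICER-WT and by 0.292 with DICER-delHelicase. These copies share an identical stretch in their 3′ part, so their reads may not be separable. The cause of the difference was not tested.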

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

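The match on the DICER-WT score, the limit of 0.05 and the restrictions to miRNAs with a single hairpin or to offset 0 were tests chosen after the data were seen. The median change over all hairpins stayed above 0 in the 5 alternatives run for it, but its size depended on the summary: 0.0261 over all hairpins became 0.103 as a mean and 0.154 among hairpins with a mean score above the median; the cause was not tested. Among changes of at least 0.05 the share of hairpins that were higher was 80.0% instead of 72.1%. If scores cannot go below 0, hairpins with a DICER-WT score under 0.05 could pass that limit only upward. For the miR-17-92 list the median change of 0.0027 turned to -0.0010 as a mean and to -0.0539 when only its 1 hairpin with a mean score above the median (mir-93) was kept; the cause was not tested. In the miR-15 and miR-16 list of 3 hairpins the median change of 0.0004 became 0.134 as a mean and 0.201 over its 2 hairpins with a mean score above the median. In the 1 hairpin of the miR-200 list, and the 1 of the miR-99, miR-100 and miR-125 list, above that median the change was 0.156 and -0.102. The miR-30 percentile of 98.0 became 95.5 when random lists were matched on the DICER-WT score, which is below the 97.5 percentile. That match moved the percentile of the miR-23, miR-27 and miR-24 list from 28.9 to 63.8, and that of the miR-148 and miR-152 list from 17.4 to 8.22. Of the 60 alternative values, 54 were classed as unchanged, some of them named above. Changes and shares so classed kept their direction and stayed within the interval of the main value. Percentiles so classed only stayed on the same side of the 2.5 and 97.5 percentiles, so the move from 28.9 to 63.8 is among them. For lists of few hairpins the interval spans nearly all members, so this says little. No paired analysis was possible because the table holds 1 value per hairpin and construct and no replicate. For this reason leaving out replicates, the replicate block, count normalization, filters on low counts, coverage minimums, the scale, measure and test of site usage, camera or fry with an estimated correlation, and arm-ratio pseudocounts were not run. The unknown depth limits the reading of scores near 0 and of small changes.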

Other observations

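The tests on copies, on scores near 0, on the reference point of the score and on a distance from position 0 were chosen after the result was seen, and the follow-up tests of the loop relation were chosen once that relation was known. Several hairpins outside the fixed lists followed the 10 largest increases and are named here after their values were seen. The variation scores were 0.412 with DICER-WT and 0.924 with DICER-delHelicase for mir-500a, 0.403 and 0.912 for mir-330, 0.377 and 0.868 for both mir-199a copies, 0.139 and 0.605 for mir-132, 0.337 and 0.790 for mir-31, and 0.349 and 0.784 for mir-1307. At the other end, 11 hairpins scored under 0.005 with both constructs, among them mir-221, mir-148a and mir-27a (0.00168 and 0.00253). A score of exactly 0 was listed for 6 hairpins with DICER-WT and for 5 with DICER-delHelicase. For the miR-30 family, 2 further tests were run, on the DICER-WT score level and on shared reads; they were withdrawn from the weighing of explanations after their values were seen, so no verdict is drawn from them. In 4.92% of the random lists matched on the DICER-WT score the median change was as large, against a bound of 5% set before that value was seen; this is the same match that put the list at the 95.5 percentile, below 97.5. The DICER-WT scores of its members spanned 0.379, against at most 0.353 between copies of a miRNA, a value that comes from let-7a alone and is 0.0197 without it; the test on shared reads was chosen after the result was seen.

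The increase in most hairpins was tested against simple properties of the table. It does not rest on copies counted several times, since the lower 95% bound of the share higher among the 111 miRNAs with a single hairpin was 58.96%. Nor does it rest on scores near 0 alone, since that bound was 62.38% among the 73 hairpins with a mean score above the median, a split that uses the scores of both constructs. Split by DICER-WT score into 5 groups of 29 or 30, from lowest to highest, the share higher was 76.7%, 72.4%, 86.7%, 69.0% and 55.2%, and the 95% intervals of the last 2 groups (49.2 to 84.7 and 35.7 to 73.6) included 50%. The median changes of these groups were 0.0034, 0.0254, 0.0893, 0.143 and 0.114, and a split on the DICER-WT score alone builds in a fall-back of the highest group. What stays open is the reference point of the score. If it counts distances from the main DICER-WT end in both groups, high delHelicase scores such as the 27 above 0.5 could stand for ends that moved together rather than for scattered ends, and the table cannot tell these apart because it holds no read positions. In that case the reference could also favour higher delHelicase scores. Part of the increase in most hairpins could then be built in, which was not tested.

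A hypothesis set before folding the hairpins was that the change relates to the size of the apical loop, since the helicase domain of DICER is thought to lie near the loop. The predicted loop and the change were inversely related over 127 miRNAs (Spearman's rho -0.3029, permutation p = 0.0007, 0.0028 after Benjamini-Hochberg adjustment over 4 features; Pearson's r -0.240, permutation p = 0.0064, and -0.222 without the 2 miRNAs with the most extreme loops). Loops of 3 to 4 nt had a median change of 0.128 (24 of 28 miRNAs higher), loops above 4 and up to 7 nt one of 0.0653 (35 of 45 higher), and loops of 8 to 17 nt one of 0.0026 (30 of 54 higher, 22 lower). The relation was -0.3164 after removing the DICER-WT score rank and -0.3168 with 1 value for each of 103 miRNA name roots. It was -0.2898 when flanks of 10 nt were removed before folding. Flanks were removed only in the 139 hairpins with 10 nt on each side, and the others were folded whole. All these values lay outside the middle 95% of shuffles. The rho values for GC content (-0.0003), folding energy per nucleotide (-0.0328) and sequence length (0.106) lay within the middle 95% of shuffles, and so did those of the loop with the DICER-WT score (0.0831) and with the DICER-delHelicase score (-0.083) taken alone. MiRNAs are not independent replicates, and each score lacks a replicate. The unknown reference point of the score limits the reading of these changes as well. The loops are predictions for the whole hairpin rather than measured precursors, and they cover only the innermost unpaired run. Copies with nearly equal scores can differ in it, as mir-3158-1 (4 nt) and mir-3158-2 (15 nt) did before averaging. A larger effect of the helicase domain on hairpins with small predicted loops may therefore be taken only as a hypothesis from these data.

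The lower delHelicase scores of 5 of the 7 hairpins whose main DICER-WT end was off position 0 may come from their high starting scores. In 7.64% of 10000 sets of offset-0 hairpins drawn from the 10 nearest DICER-WT scores, at least 5 of 7 were lower. This does not settle it, because 3 of the 7 (mir-10399, mir-145 and mir-324, which had the largest decreases of the set) scored above 0.685, the highest DICER-WT score among offset-0 hairpins, and so had no match. High starting scores and the offset therefore cannot be told apart for these hairpins. A mean absolute distance from position 0, taken over the same pooled reads as the main end, is excluded as the score by mir-16-2. Its DICER-WT score of 0.199 would then leave at least 80.07% of reads at position 0, yet its main end is listed at -1. This holds only if the offset is counted in nucleotides from position 0, as read here. A score averaged over samples is not excluded in this way, because how the samples were combined is not given. With 7 hairpins and no read positions, a true shift of the main end in these hairpins was not tested.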
